A study of Homo sapiens with 12 samples.

How the data were processed

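Total RNA of HepG2 cells, 200 ng per array and extracted with TRI reagent, was labelled with biotin and hybridised to Affymetrix Human Gene arrays, per the labels' protocols. Cells had been plated as biological duplicates at 700000 per well and treated for 24 h with DMSO, 10 uM Nutlin or 0.5 mM AICAR. The hairpin and the treatment of each array were taken from its title, giving 6 groups of 2 arrays, and each of the 12 columns of values matched 1 title, with 0 columns left over. The deposited values were on the log2 scale, from 2.14 to 14.33, with 1 value per probe set and array. The submitters' processing notes name RMA, the robust multi-array average, which corrects background, normalises the arrays by quantiles and summarises the probes of a set, and they name Partek. Versions of both, and the settings used, were not given in the sources used here. RMA forces the arrays towards a common distribution, so a change of most transcripts in one direction would be removed in part. Its values carry no detection call, a low value holds mostly background, and changes of dim genes are understated. Where the lower group's mean lay below the level used to leave out dim genes, as for NRCAM, KITLG and AQP9 with the hairpin in DMSO, ZSCAN4 with AICAR, and MUC13, CCNE2, SPC25, CDK1 and ABCA12 in Nutlin against AICAR, the size of the change is uncertain.

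In all, 33297 probe sets had values. The platform annotation, which can be old, paired 19460 with 1 gene symbol and 1754 with several, and did not list 12083, which are unnamed here. The RefSeq table of assembly GRCh38.p14 had an entry for 19429 of the single symbols, and was used for names and for the length of a gene's locus, with no coordinates taken from it. A gene was measured by its brightest probe set with 1 symbol, the one with the highest mean over the 12 arrays. This gave 18417 genes, 769 of them with more than 1 probe set. Genes with a mean under the 25th percentile (4.58 on the log2 scale) were left out, 4604 in number, and 13813 were tested. Probe sets of 1 gene can disagree: ATF4 fell by 1.96 with AICAR in sh-con by the brightest and by 0.71 by the other, and PTCHD4 fell by 1.63 and 2.65 with the hairpin in DMSO. The transcript targeted by the hairpin was not analysed here.

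Group means of all 12 arrays were fitted in 1 linear model with limma 3.58.1 in R 4.3.3, with the package data.table (version 1.17.8), since 2 arrays per group give too few degrees of freedom to estimate the spread of a single comparison well. The fit had 6 residual degrees of freedom, to which the empirical Bayes step added 11.3 from a prior SD of 0.154. Errors given as ± SE are those of the fit. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 8 comparisons, 2-sided. Comparisons were sh-p53 against sh-con in DMSO, each compound against DMSO in each line, the difference of each compound's response between the lines as an interaction, and Nutlin against AICAR in sh-con. Fold changes are on the log2 scale unless called fold. The 28 gene lists, drawn from textbook knowledge, covered p53 targets, the cell cycle, liver metabolism and secretion, stress and signalling responses, reference genes and markers of other cell types. They were tested with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation, and their members were also counted with p-values adjusted over the list alone. The median, mean and camera direction of a list differed in sign for 6 lists in the DMSO comparison of the hairpins, 1 and 5 with Nutlin and AICAR in sh-con, 4 and 3 in sh-p53, 2 and 8 in the interactions and 2 between the compounds; none of these lists was called.

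Named genes followed a rule. Named in each comparison were genes among the 8 highest and the 8 lowest log2 fold changes of called genes in which every array of one group lay beyond every array of the other, with no such condition for interactions. For each list up to 4 called members with the largest changes were eligible, a gene named in one comparison could be given in another, and CDKN1A and MDM2 were given throughout. With 2 arrays against 2, unchanged groups do not overlap in 33.3% of draws. The groups, the test, the lists, the naming rule and the alternatives were fixed before the data were examined. The overlap of the responses to the compounds was set beside n1 × n2 / N for independent lists and beside 50 simulations of unchanged groups. In these, all arrays were simulated and both compounds were compared with the same simulated DMSO arrays. The overlap of the interactions was set beside 50 simulations from the fitted group means with the AICAR interaction set to 0. These called more negative Nutlin interactions (mean 981) than the data. Noise was added to means that already held it, but whether that caused the excess was not tested. The simulations of the interactions were added after the data had been seen. Alternatives were leaving out each array in turn, fitting only the arrays compared, no filter and a stricter filter (50th percentile) on dim genes, the mean over probe sets, every probe set separately, quantile normalisation again, centring each array on its median, a trended and robust prior, no moderation, the replicate number as a block, a minimum of 1.5-fold and an estimated correlation of the lists.

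The procedure was tested on simulated data with the spread of the real arrays. For Nutlin in sh-con, 36% of 50 genes changed by 0.5 on the log2 scale were recovered and 100% of those changed by 1 or more, and 12 of 13613 unchanged genes were called. For the interaction of Nutlin with the hairpin the shares were 8% at 0.5, 82% at 1 and 100% above, with 7 unchanged genes called. In the list test the 1 shifted list was called and 0 of 27 others. The simulated genes varied independently and the lists were random. The estimated correlation of the real lists was 0.27 for p53 targets and 0.59 for mitosis genes, for example. The simulation therefore does not show how often the list test calls unchanged lists of correlated genes. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.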

Results

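Transcript levels were measured in HepG2, an established human hepatoma cell line, carrying either a small-hairpin RNA against p53 (sh-p53) or a control hairpin (sh-con). Each line was treated for 24 h with DMSO as the solvent control, with 10 uM Nutlin or with 0.5 mM AICAR, and the design names both compounds as stimulators of p53. Nutlin blocks the binding of p53 to MDM2, the ubiquitin ligase that drives its degradation, and AICAR activates the energy-sensing kinase AMPK. The line and the treatment together gave 6 groups of 2 Affymetrix arrays each, from cells plated as biological duplicates, and the number of arrays limits the precision of every comparison. The median over all probe sets lay between 5.64 and 5.84 on the log2 scale in the 12 arrays. The 2 arrays of a group correlated across genes at Pearson r = 0.983 to 0.994. The SD of their difference ranged from 0.19 on the log2 scale in the sh-con DMSO arrays to 0.302 in the sh-con AICAR arrays. On the first principal component, which held 47% of the variance, the 4 AICAR arrays scored from 33.9 to 45.2 and the other 8 from -24.7 to -14.9. On the second, which held 33.8%, the sh-con Nutlin arrays scored -46.6 and -52.9 and the other 10 from -13.8 to 25.9.

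The transcript of the targeted gene was not analysed here, so known p53 target genes served as the check on the hairpin labels. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, stood at 7.06 and 6.93 on the log2 scale in the sh-con DMSO arrays and at 6.14 and 6.32 in the sh-p53 DMSO arrays. With Nutlin it reached 9.92 and 9.76 in sh-con and 7.61 and 7.63 in sh-p53. With AICAR it reached 9.31 and 9.21 in sh-con and 8.02 and 7.96 in sh-p53. MDM2, itself a p53 target, stood at 10.63 and 10.47 in sh-con DMSO and at 9.78 and 9.96 in sh-p53 DMSO. Its Nutlin values were 12.07 and 12.21 in sh-con and 11.20 and 11.17 in sh-p53, and its AICAR values were 11.25 and 11.25 in sh-con and 9.96 and 10.12 in sh-p53. TP53I3, a p53-induced quinone oxidoreductase gene, stood at 7.98 and 8.06 in sh-con DMSO and at 7.56 and 7.78 in sh-p53 DMSO. It reached 11.53 and 11.50 with Nutlin in sh-con, against 8.35 and 7.88 in sh-p53, and 11.13 and 11.02 with AICAR in sh-con, against 8.12 and 8.36 in sh-p53. Under every treatment, both sh-p53 arrays lay below both sh-con arrays for each of these 3 genes.

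**Figure D1:**
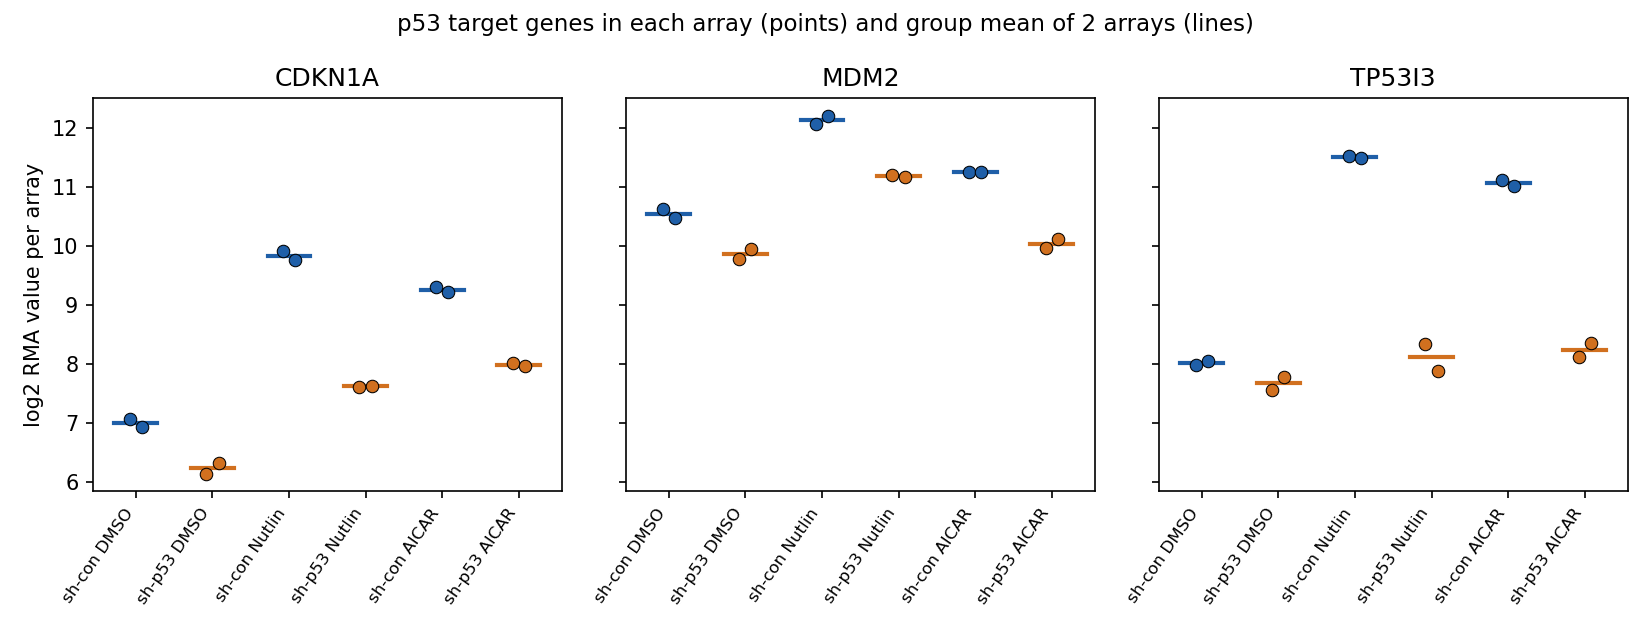
The log2 RMA value of CDKN1A, MDM2 and TP53I3 in each array (points) and the mean of the 2 arrays of a group (lines), with sh-con in blue and sh-p53 in orange. CDKN1A stood at 9.92 and 9.76 in the sh-con Nutlin arrays and at 7.61 and 7.63 in the sh-p53 Nutlin arrays.

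The first comparison set sh-p53 against sh-con in DMSO, asking how the lines differed without a stimulator. The labels name no further line for either hairpin. Knockdown of p53 therefore cannot be told apart from other differences between the lines, here or in the interactions. Errors and p-values measure the spread between duplicate arrays, not between independently made lines. Changes given below as those with the hairpin are differences between these lines. PLA2G2A, which encodes a secreted phospholipase, rose most, with a log2 fold change of 3.42 ± 0.16 (SE, 2 arrays against 2, adjusted p = 6.05e-10). NRCAM, a neuronal cell adhesion gene, rose by 1.60 ± 0.14, KITLG, the ligand of the KIT receptor, by 1.51 ± 0.18, and NR5A2, a nuclear receptor of bile acid synthesis, by 1.43 ± 0.18. TSPAN7 fell by 2.69 ± 0.14, the glutathione transferase gene GSTA1 by 2.65 ± 0.15 (adjusted p = 3.91e-09), the glycerol and urea channel gene AQP9 by 1.77 ± 0.17 and the heparan sulfatase gene SULF2 by 1.67 ± 0.15. In all, 36 genes were higher and 53 lower at an adjusted p under 0.05, of which 18 and 22 changed at least 2-fold. GSTA1 and AKR1C2, which fell by 1.45 ± 0.17, belong to families of near-identical genes, and a probe set of such a family can also measure its relatives.

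Of the 58 tested genes of the p53 target list (65 members), 9 fell and 1 rose, and 48 did not pass; adjusted over the list alone, 12 fell and 1 rose. SPATA18, a mitochondrial quality control gene, fell 2.84-fold (adjusted p = 9.62e-05) and KITLG rose, and the median log2 fold change of the list was -0.20 (camera, adjusted p = 2.28e-14; adjusted p = 0.482 with an estimated correlation). The cytochrome P450 and drug metabolism list had 4 of 35 tested genes lower, GSTA1 and CYP24A1 (-1.15 ± 0.17) among them, and 10 lower when adjusted over the list alone. Its median was -0.26 (adjusted p = 4.54e-14; adjusted p = 0.238 with an estimated correlation). No gene of the 38 hepatocyte secreted protein genes passed over all genes with limma (2 higher and 11 lower at an unadjusted p under 0.05); adjusted over the list alone, 1 rose and 8 fell, and the median was -0.16 (adjusted p = 2.09e-06; adjusted p = 0.608 with an estimated correlation). None of the 42 S phase or 48 mitosis genes passed with limma, over all genes or adjusted over the list alone, and 0 and 2 had an unadjusted p under 0.05. The mitosis list was nevertheless called higher by camera, with a median of 0.0932 (adjusted p = 0.00352; adjusted p = 0.95 with an estimated correlation), a call lost without sh-con DMSO array 2 (adjusted p = 0.228) or sh-p53 DMSO array 2 (0.581). Over the lists, 9 of 28 passed the camera test with the preset correlation, and none passed with an estimated correlation (lowest adjusted p = 0.238), as in the other 7 comparisons. CDKN1A fell by 0.76 ± 0.13 (adjusted p = 0.00625), a call lost without sh-con DMSO array 1 (adjusted p = 0.181) or sh-p53 DMSO array 1 (adjusted p = 0.18). MDM2 fell by 0.68 ± 0.14 (adjusted p = 0.0178), a call lost without sh-con DMSO array 1 (0.392), sh-con DMSO array 2 (0.0784), sh-p53 DMSO array 1 (0.332) or sh-p53 DMSO array 2 (0.0775). The count of genes that rose was 22 without sh-con DMSO array 1, 22 without sh-con DMSO array 2 and 22 without sh-p53 DMSO array 2. The count of genes that fell was 20 without sh-con DMSO array 1, 23 without sh-p53 DMSO array 1 and 29 without sh-p53 DMSO array 2.

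Nutlin in the sh-con line gave the response to the compound where the hairpin did not target p53. The lipid transporter gene ABCA12 rose, with the highest fitted log2 fold change of 3.91 ± 0.13 (SE, 2 arrays against 2, adjusted p = 8.56e-13). The hyaluronan receptor gene LYVE1 (3.65 ± 0.18) and the phospholipid transfer protein gene PLTP (3.51 ± 0.15) were also among the 8 highest. ABCA12, LYVE1 and TRIM22 had a mean in DMSO below the level used to leave out dim genes, as SPC25, CLSPN and CDK1 had with Nutlin, so the size and rank of these changes are uncertain. Among p53 targets, TP53I3 rose by 3.50 ± 0.16, TRIM22 by 3.14 ± 0.17, CDKN1A by 2.84 ± 0.13 (adjusted p = 2.67e-11) and MDM2 by 1.59 ± 0.14 (adjusted p = 6.12e-08). The histone gene H2BC14 fell by 4.69 ± 0.15 (adjusted p = 5.78e-13), and also among the 8 lowest were the kinetochore gene SPC25 (-4.48 ± 0.20), the replication checkpoint gene CLSPN (-4.28 ± 0.14) and the replication licensing gene CDC6 (-3.92 ± 0.16). CDK1, the kinase that drives entry into mitosis, fell by 3.92 ± 0.20, and RRM2, a subunit of ribonucleotide reductase, fell by 3.69 ± 0.21.

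Of 58 tested p53 target genes, 55 rose and none fell, also at an unadjusted p under 0.05, with a median of 1.17 (camera, adjusted p = 4.11e-35; adjusted p = 0.0976 with an estimated correlation); adjusted over the list alone, 56 rose. All 48 tested mitosis genes fell, BUB1 (-3.77 ± 0.15) and NUF2 (-3.77 ± 0.16) among them, with a median of -3.07 (adjusted p = 1.58e-59; adjusted p = 0.0976 with an estimated correlation). In the S phase list, 40 of 42 fell, with a median of -2.21 (adjusted p = 3.48e-41; adjusted p = 0.0976 with an estimated correlation); the counts adjusted over the list alone were the same for both lists. Of 36 ribosome biogenesis genes 29 fell, UTP20 (-1.35 ± 0.17) and NOLC1 (-1.14 ± 0.13) among them, with a median of -0.71 (adjusted p = 3.91e-12; adjusted p = 0.511 with an estimated correlation); adjusted over the list alone, 31 fell. Of 28 purine and pyrimidine synthesis genes 17 fell and 3 rose, as adjusted over the list alone, and the median was -0.51 (adjusted p = 0.000274; adjusted p = 0.708 with an estimated correlation). MTHFD1, a folate enzyme that supplies purine synthesis, fell by 1.52 ± 0.14. In the P450 and drug metabolism list 19 of 35 rose and 1 fell, with a median of 0.43 (adjusted p = 2.07e-07; adjusted p = 0.254 with an estimated correlation); adjusted over the list alone, 21 rose and 2 fell. CYP3A5, a steroid and drug hydroxylase, rose by 2.56 ± 0.17, and the fatty acid hydroxylase CYP4F2 by 2.35 ± 0.17, both from families of near-identical genes.

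Smaller parts of the other lists passed with Nutlin in sh-con. Of 24 gluconeogenesis and glucose output genes 7 rose and 1 fell, and G6PC1, the last enzyme of glucose output, rose by 1.89 ± 0.15; adjusted over the list alone, 8 rose and 1 fell. Of 27 fatty acid oxidation genes 6 rose and 2 fell (7 and 2 adjusted over the list alone), and CPT1A, which admits fatty acids to mitochondria, rose by 1.31 ± 0.17. MTTP, needed for lipoprotein assembly, fell by 2.34 ± 0.16, and ELOVL6, a fatty acid elongase, by 1.62 ± 0.14. NUPR1, a stress-induced nuclear protein gene of the amino acid response list, rose by 2.99 ± 0.16. Of the 6 tested endothelial markers LYVE1 and ENG (0.95 ± 0.15) rose, also when adjusted over the list alone, and the list's call (median 0.33, adjusted p = 0.0139; adjusted p = 0.254 with an estimated correlation) was lost when the arrays were quantile normalised again (adjusted p = 0.0644) or with the stricter filter on dim genes (adjusted p = 0.557). None of 6 fibroblast markers passed with limma (2 higher at an unadjusted p under 0.05) and 1 of 5 leukocyte markers rose, with the same counts adjusted over the list alone. Of 10 cholangiocyte and progenitor markers 1 rose and 3 fell, also adjusted over the list alone. Of 22 reference genes 7 fell, also adjusted over the list alone, with a median of -0.21 that became -0.0685 after quantile normalisation again and -0.104 after centring each array on its median; TUBB, a tubulin gene among them, fell by 1.19 ± 0.13.

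Across all 13813 genes tested, 1563 rose and 2616 fell with Nutlin in sh-con, of which 257 and 576 changed at least 2-fold, and higher genes made up 37.4% of the calls. Scaling moved this split, and the log2 fold changes of single genes in sh-con shifted by a median of 0.101 to 0.11 under other scalings, for either compound: it was 2025 and 2185 genes (48.1%) after quantile normalisation of the arrays again, and 2333 and 2118 (52.4%) after centring each array on its median. Without sh-con DMSO array 1 the counts were 737 and 1324, and without sh-con Nutlin array 2 they were 849 and 1340. Of the 53 genes that fell with the hairpin in DMSO, 29 rose with Nutlin in sh-con, against 6.00 for independent lists; the sh-con DMSO arrays entered both comparisons and favour changes of the same sign, not of opposite sign.

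AICAR in the sh-con line gave the response to the other stimulator. The mucin gene MUC13 rose, with the highest fitted log2 fold change of 4.59 ± 0.18 (SE, 2 arrays against 2, adjusted p = 1.39e-11), from a mean in DMSO below the level used to leave out dim genes, as for CABYR. CABYR, which encodes a calcium-binding protein, rose by 4.07 ± 0.14, the arrestin-related gene ARRDC4 by 3.92 ± 0.19, and HBEGF, a ligand of the EGF receptor, by 3.62 ± 0.14. The p53 targets PMAIP1, a pro-apoptotic BCL2-family gene, and TP53I3 rose by 3.33 ± 0.18 and 3.06 ± 0.16, CDKN1A by 2.27 ± 0.13 (adjusted p = 2.25e-09) and MDM2 by 0.69 ± 0.14 (adjusted p = 0.000603). PTPRK, a receptor tyrosine phosphatase gene, fell by 3.17 ± 0.19 (adjusted p = 2.19e-09), with the protein kinase C gene PRKCA (-3.12 ± 0.16) and the phospholipase gene PLCB1 (-3.02 ± 0.16). The cystine transporter gene SLC7A11 fell by 2.36 ± 0.19 and ATF4, the transcription factor of the amino acid response, by 1.96 ± 0.15.

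Of 58 p53 target genes 42 rose and 2 fell, with a median of 0.99 (camera, adjusted p = 7.7e-18; adjusted p = 0.881 with an estimated correlation); adjusted over the list alone, 42 rose and 3 fell. Cell cycle genes went both ways. Of 42 S phase genes 8 rose and 16 fell (9 and 17 adjusted over the list alone), CCNE2, a cyclin of S phase entry, at 2.05 ± 0.19 and MCM3, a replicative helicase gene, at -1.29 ± 0.15. Of 48 mitosis genes 11 rose and 9 fell, as adjusted over the list alone, CENPE at 1.25 ± 0.19 and BUB1B at -0.93 ± 0.17. In the cholesterol synthesis list 11 of 19 rose, also adjusted over the list alone, IDI1 (1.52 ± 0.14) and SC5D (1.17 ± 0.14) among them, with a median of 0.52 (adjusted p = 0.000135; adjusted p = 0.948 with an estimated correlation). Of 37 amino acid response genes 19 fell and 4 rose, with a median of -0.40 (adjusted p = 0.00624; adjusted p = 0.948 with an estimated correlation); adjusted over the list alone, 20 fell and 4 rose. Within that list SESN2 (1.89 ± 0.14), a stress-induced inhibitor of mTORC1 signalling, and NUPR1 (1.72 ± 0.16) rose. In the ribosome biogenesis list 26 of 36 fell, UTP20 (-1.76 ± 0.17) and MYC (-1.11 ± 0.14) among them, with a median of -0.62 (adjusted p = 1.18e-07; adjusted p = 0.948 with an estimated correlation); adjusted over the list alone, 28 fell. Of 28 purine and pyrimidine synthesis genes 16 fell and 1 rose, with a median of -0.48 (adjusted p = 0.00341; adjusted p = 0.948 with an estimated correlation); adjusted over the list alone, 17 fell and 1 rose. ADK, the adenosine kinase gene, fell by 1.41 ± 0.19.

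Among metabolic genes, the glucose transporter gene SLC2A2 fell 2.84-fold (adjusted p = 7.04e-07) and PPARGC1A, a coactivator of gluconeogenic genes, fell by 1.10 ± 0.15 on the log2 scale with AICAR in sh-con. Of 24 gluconeogenesis and glucose output genes 8 fell and 3 rose (8 and 4 adjusted over the list alone). With limma 8 were higher and 8 lower at an unadjusted p under 0.05, and the largest rise was 1.70. The list as a whole was not called, with a median of 0.133 (camera, adjusted p = 0.996). Of 24 oxidative stress (NRF2) genes 10 fell and 1 rose, as adjusted over the list alone, and the transporter gene ABCC2 fell by 1.17 ± 0.15. The NRF2 list was not called either (median -0.179, camera, adjusted p = 0.141). Of 35 autophagy and lysosome genes 7 rose and 2 fell, as adjusted over the list alone; NEU1, a lysosomal sialidase, rose by 1.45 ± 0.14 and MAP1LC3B, an autophagosome protein gene, by 1.22 ± 0.15. None of 6 endothelial or 6 fibroblast markers passed with limma, over all genes or adjusted over the list alone, 1 and 2 were higher at an unadjusted p under 0.05, and LYVE1 stood at 0.35 ± 0.18 (adjusted p = 0.136). Of 5 leukocyte markers 2 rose, and of 10 cholangiocyte and progenitor markers 1 rose and 2 fell, also adjusted over the list alone. In all, 2023 genes rose and 3198 fell, 337 and 802 of them at least 2-fold, and higher genes made up 38.7% of the calls. Quantile normalisation again gave 2625 and 2877 genes (47.7%), and centring each array on its median gave 2996 and 2746 (52.2%). Without sh-con DMSO array 1 the counts were 1164 and 2009.

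**Figure D2:**
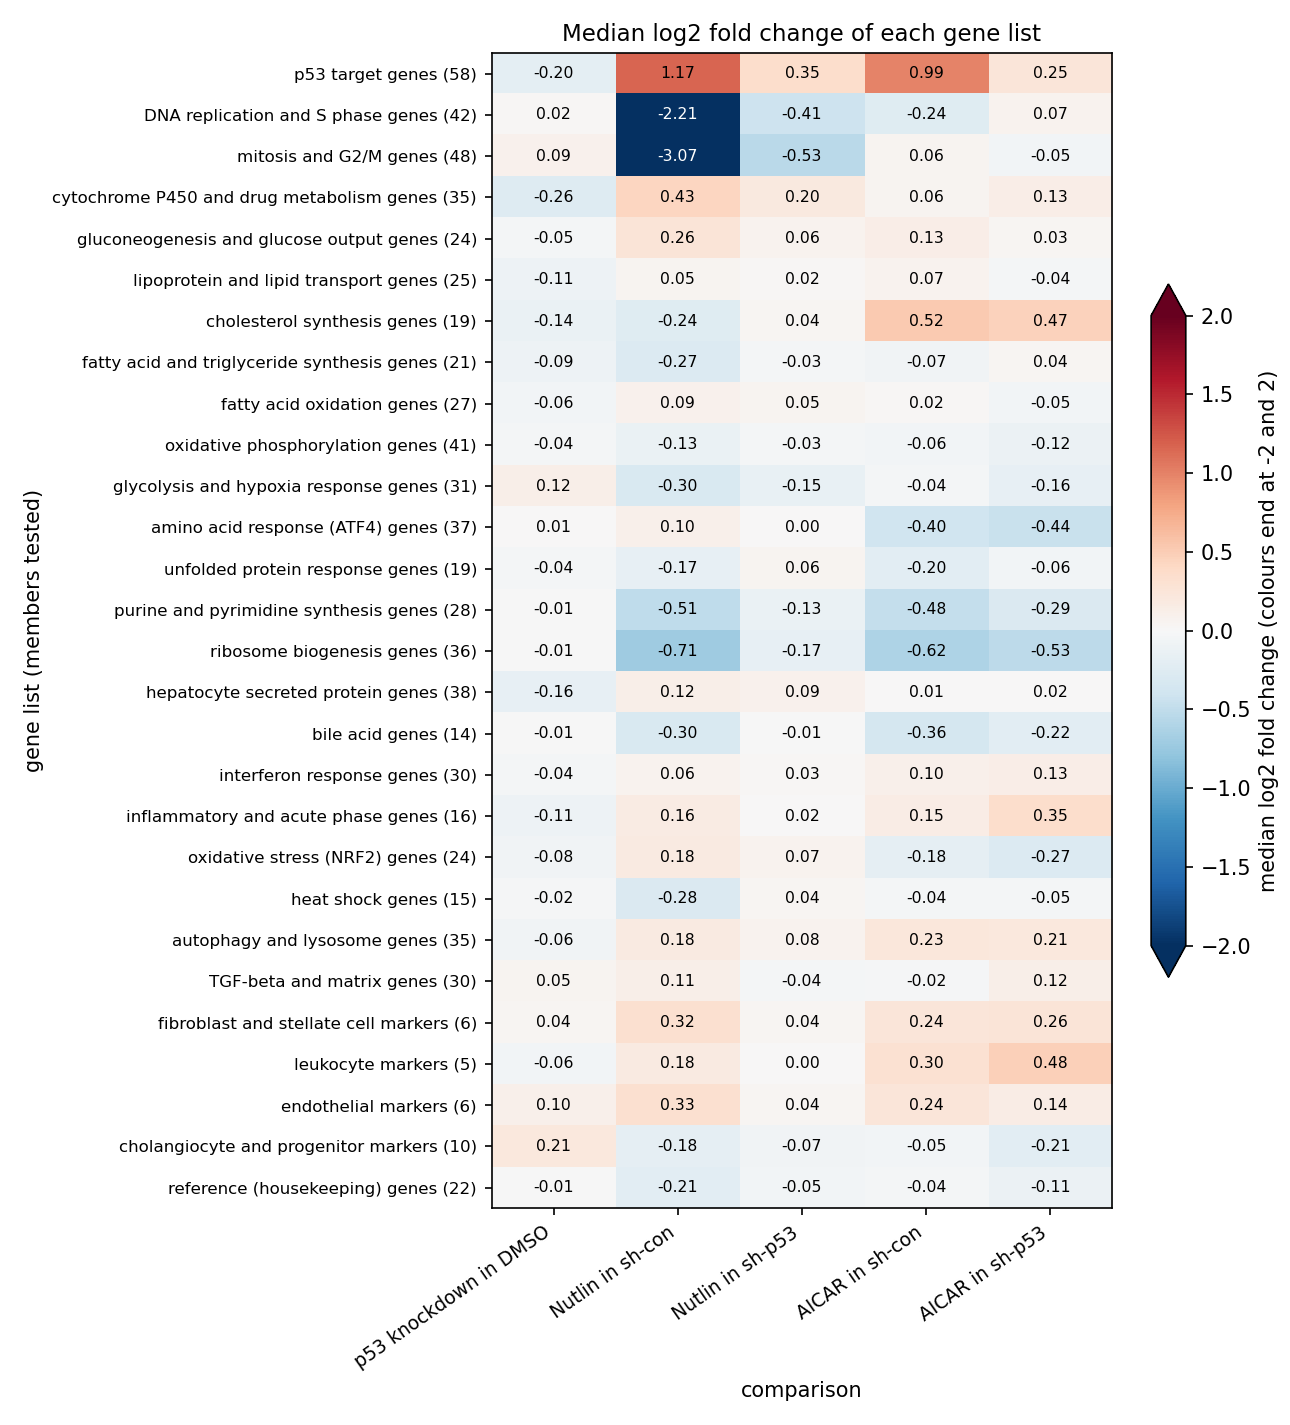
The median log2 fold change of each gene list, with the number of members tested in brackets, in 5 comparisons against the matching control; red is higher and blue is lower. The mitosis list stood at -3.07 with Nutlin in sh-con and at -0.53 with Nutlin in sh-p53, and the cholesterol synthesis list at 0.52 and 0.47 with AICAR in the sh-con and sh-p53 lines.

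Nutlin in the sh-p53 line changed few genes past the threshold. CDKN1A rose by 1.39 ± 0.13 (SE, 2 arrays against 2, adjusted p = 6.67e-05), TP53INP1, a p53-induced stress protein gene, by 1.36 ± 0.13, the smooth muscle actin gene ACTA2 by 1.35 ± 0.16 and MDM2 by 1.32 ± 0.14 (adjusted p = 9.08e-05). These 4 calls held with any of the 12 arrays left out. SPATA18 (1.23 ± 0.17), the globin gene CYGB (1.12 ± 0.16), the sulfotransferase gene SULT2A1 (1.09 ± 0.16) and the RNA-binding p53 target ZMAT3 (0.94 ± 0.13) also rose. In all, 11 genes rose and none fell with limma, whereas 296 rose and 564 fell at an unadjusted p under 0.05. Quantile normalisation of the arrays again gave 19 and 4 genes (82.6% higher), fitting only the arrays compared 29 and 38, the stricter filter on dim genes 16 and 12, the trended and robust prior 16 and 10, and no moderation 4 and 0. All 11 genes were also called higher with Nutlin in sh-con, against 1.24 for independent lists.

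Of 58 p53 target genes 6 rose with Nutlin in sh-p53, and 27 rose when adjusted over the list alone, with a median of 0.35 (camera, adjusted p = 1.96e-39; adjusted p = 0.144 with an estimated correlation). None of 42 S phase genes passed over all genes with limma (34 lower at an unadjusted p under 0.05), whereas 32 fell when adjusted over the list alone, with a median of -0.41 (adjusted p = 3.27e-30; adjusted p = 0.144 with an estimated correlation). None of 48 mitosis genes passed over all genes with limma (42 lower at an unadjusted p under 0.05) and 41 fell when adjusted over the list alone, with a median of -0.53 (adjusted p = 4.47e-45; adjusted p = 0.144 with an estimated correlation). Of 35 P450 and drug metabolism genes 1 rose, and 5 rose when adjusted over the list alone, with a median of 0.20 (adjusted p = 1.87e-10; adjusted p = 0.144 with an estimated correlation). The count of genes that rose was 5 without sh-p53 DMSO array 1, sh-p53 DMSO array 2 or sh-p53 Nutlin array 1, and 9 genes fell without sh-con AICAR array 1 or 2, which enter through the shared estimate of the spread. The call of SPATA18 was lost without sh-p53 DMSO array 2 (adjusted p = 0.0846) or sh-p53 Nutlin array 1 (0.0911), and that of SULT2A1 without sh-p53 DMSO array 1 (0.284) or sh-p53 Nutlin array 1 (0.123). CYGB was lost without sh-p53 DMSO array 1 (adjusted p = 0.0926), sh-p53 DMSO array 2 (0.0846) or sh-p53 Nutlin array 2 (0.117). ZMAT3 was lost without sh-p53 DMSO array 1 (adjusted p = 0.0926), sh-p53 DMSO array 2 (0.0846) or sh-p53 Nutlin array 1 (0.0787).

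AICAR in the sh-p53 line gave a broad response. ARRDC4 rose by 3.98 ± 0.19 (SE, 2 arrays against 2, adjusted p = 3.4e-10), MUC13 by 3.34 ± 0.18 and HBEGF by 3.23 ± 0.14. SLC7A11 fell by 3.30 ± 0.19 (adjusted p = 3.76e-09), IGFBP1, a secreted binding protein of insulin-like growth factors, by 3.20 ± 0.22 and ATF4 by 2.27 ± 0.15. PMAIP1 rose by 2.27 ± 0.18, PLK3, a stress-responsive kinase gene, by 2.11 ± 0.14 and CDKN1A by 1.76 ± 0.13 (adjusted p = 4.26e-08), whereas MDM2 stood at 0.17 ± 0.14 (adjusted p = 0.33) and passed when the arrays were quantile normalised again (0.35, adjusted p = 0.0117). CCNE2 rose by 2.48 ± 0.19 and CCNE1 by 1.21 ± 0.14, both cyclins of S phase entry.

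Of 58 p53 target genes 23 rose and 7 fell with AICAR in sh-p53, as adjusted over the list alone, and the median was 0.25 (camera, adjusted p = 0.000126; adjusted p = 0.941 with an estimated correlation). Of 19 cholesterol synthesis genes 12 rose and 1 fell (13 and 1 adjusted over the list alone), IDI1 (1.53 ± 0.14) and ERG28 (1.40 ± 0.13) among them, with a median of 0.47 (adjusted p = 8.03e-05; adjusted p = 0.941 with an estimated correlation). Of 37 amino acid response genes 19 fell and 2 rose (19 and 3 adjusted over the list alone), with MTHFD2, a mitochondrial folate enzyme, at -1.64 ± 0.14 and a median of -0.44 (adjusted p = 0.000713; adjusted p = 0.941 with an estimated correlation). In the ribosome biogenesis list 24 of 36 fell and 1 rose (28 and 1 adjusted over the list alone), RRS1 (-1.33 ± 0.17) and MYC (-1.17 ± 0.14) among them, with a median of -0.53 (adjusted p = 2.02e-06; adjusted p = 0.941 with an estimated correlation). Of 5 leukocyte markers 3 rose and of 10 cholangiocyte and progenitor markers 4 fell, also adjusted over the list alone, whereas none of 6 endothelial or 6 fibroblast markers passed with limma (1 of each higher at an unadjusted p under 0.05). In all, 2235 genes rose and 2982 fell, 292 and 806 of them at least 2-fold, and higher genes made up 42.8% of the calls. Quantile normalisation again gave 2783 and 2849 genes (49.4%), and centring each array on its median gave 2564 and 2895 (47%). The count that rose was 1407 without sh-p53 DMSO array 1, 1382 without sh-p53 DMSO array 2 and 1436 without sh-p53 AICAR array 1, and the count that fell was 1925 without sh-p53 AICAR array 1.

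Whether the response to Nutlin differed between the lines was tested as an interaction, the change in sh-p53 minus that in sh-con. For the genes that fell most in sh-con the interaction was positive: H2BC14 at 4.07 ± 0.21 (SE, 4 groups of 2 arrays, adjusted p = 1.44e-09), SPC25 at 3.91 ± 0.28, CLSPN at 3.75 ± 0.19 and CDK1 at 3.28 ± 0.28. It was negative for genes that rose most in sh-con, with ABCA12 at -3.83 ± 0.18 (adjusted p = 1.25e-09), PLTP at -3.57 ± 0.21, LYVE1 at -3.45 ± 0.26 and TP53I3 at -3.05 ± 0.23. The size is uncertain for ABCA12 and LYVE1, with means below the level used to leave out dim genes in 3 of the 4 groups, and for SPC25, CLSPN and CDK1, below it in sh-con with Nutlin. CDKN1A differed by -1.46 ± 0.19 (adjusted p = 3.82e-05), whereas MDM2 stood at -0.27 ± 0.19 (adjusted p = 0.481). All 48 mitosis genes had a positive interaction past the threshold, with a median of 2.46 (camera, adjusted p = 1.26e-85; adjusted p = 0.0809 with an estimated correlation), as did 37 of 42 S phase genes (median 1.79, adjusted p = 2.83e-53; adjusted p = 0.0809 with an estimated correlation). Adjusted over the list alone, these counts were 48 and 40. Of 58 p53 target genes 31 had a negative interaction, 40 when adjusted over the list alone, with a median of -0.79 (adjusted p = 3.95e-29; adjusted p = 0.113 with an estimated correlation).

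In all, 645 genes had a positive and 377 a negative interaction with Nutlin. Quantile normalisation of the arrays again gave 763 and 664, which moved the positive share from 63.1% to 53.5%. Of the 1563 genes that rose with Nutlin in sh-con, 79.7% had a change above 0 in sh-p53, their median going from 0.58 to 0.12, and of the 2616 that fell, 90.9% had a change below 0, their median going from -0.65 to -0.18. Over the called genes the slope of the sh-p53 response on the sh-con response was 0.19, and across all genes, which are not independent replicates, the responses correlated at Pearson r = 0.64 and Spearman rho = 0.611. Choosing genes by their call in sh-con by itself favours a larger change there, so part of the smaller sh-p53 medians and slope can come from that choice. The positive count was 411 without sh-con DMSO array 1 and 420 without sh-p53 DMSO array 1. The negative count was 239 without sh-con DMSO array 2, 233 without sh-p53 DMSO array 1 and 247 without sh-con Nutlin array 1.

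**Figure D3:**
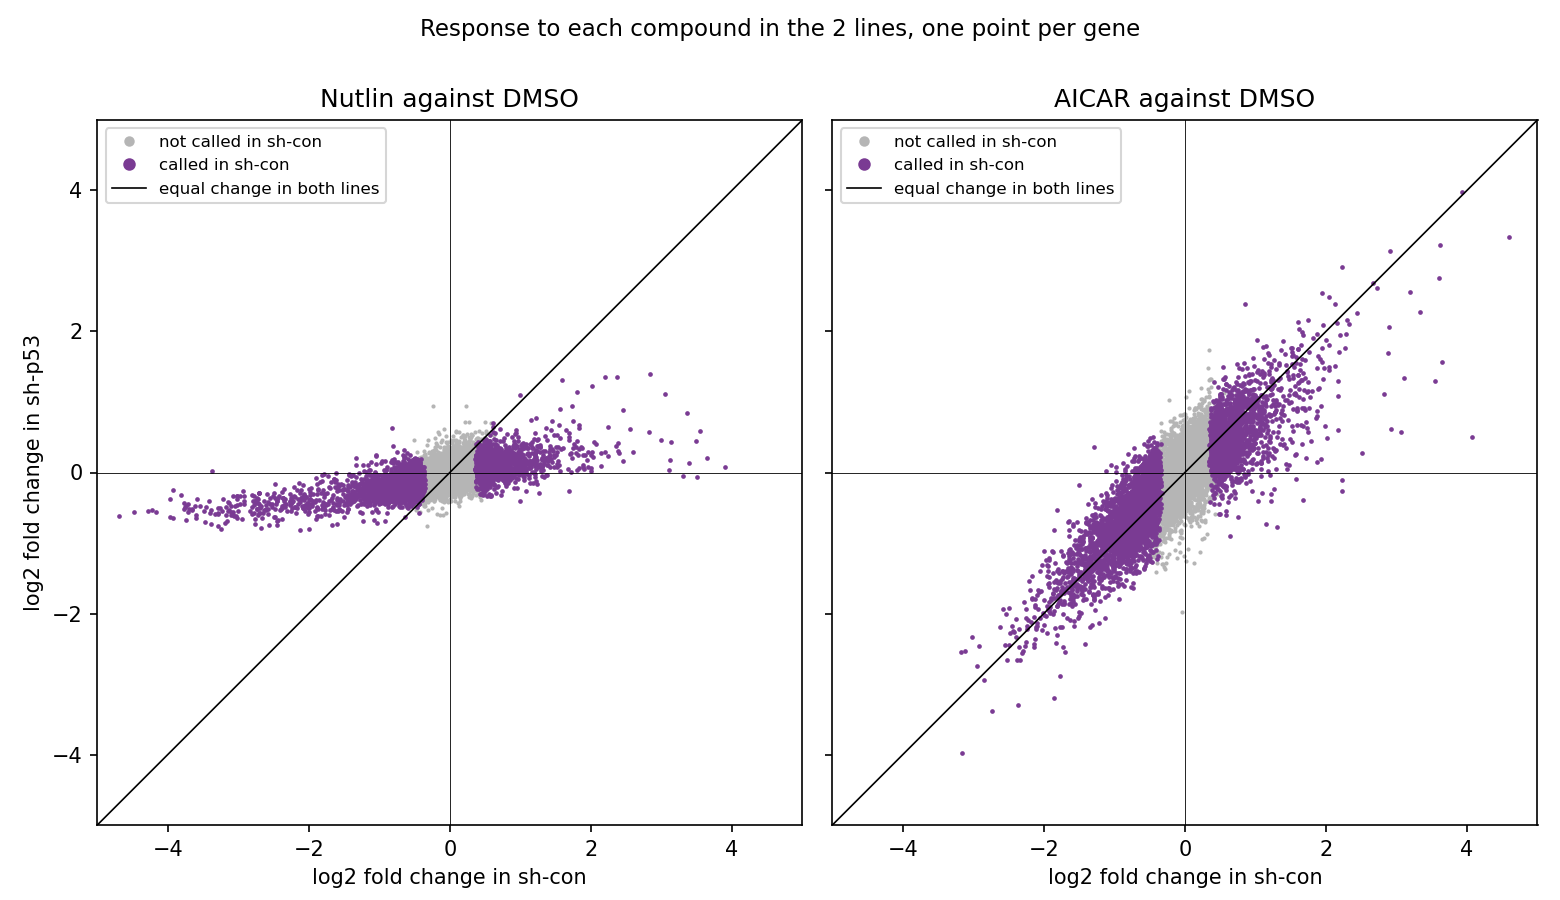
The log2 fold change of each gene in sh-con (horizontal axis) and in sh-p53 (vertical axis) with Nutlin (left) and AICAR (right); purple points passed the test in sh-con, grey points did not, and the diagonal marks an equal change. The slope over the genes called in sh-con was 0.19 with Nutlin and 0.823 with AICAR.

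For AICAR the interaction with the hairpin was called for fewer genes. TP53I3 rose less in sh-p53, with an interaction of -2.49 ± 0.23 (SE, 4 groups of 2 arrays, adjusted p = 9.21e-06), and CABYR differed by -3.57 ± 0.20 (adjusted p = 1.78e-08), the cystatin gene CSTA by -2.33 ± 0.19, ZSCAN4 by -2.25 ± 0.21 and NUPR1 by -1.51 ± 0.23; CABYR and ZSCAN4 lay below the dim level in DMSO in both lines, which leaves the size uncertain. The transcriptional cofactor gene HCFC1 (1.66 ± 0.24, adjusted p = 0.00148) and PLAU, the urokinase gene (1.55 ± 0.20), had a positive interaction. CDKN1A stood at -0.51 ± 0.19 (adjusted p = 0.24) and MDM2 at -0.52 ± 0.19 (adjusted p = 0.227). Of 58 p53 target genes 15 had a negative interaction, 26 when adjusted over the list alone, with a median of -0.47 (camera, adjusted p = 1.07e-22; adjusted p = 0.552 with an estimated correlation). In the glycolysis and hypoxia response list none of 31 genes passed over all genes with limma (1 positive and 8 negative at an unadjusted p under 0.05) and 3 were negative when adjusted over the list alone, with a median of -0.30 (adjusted p = 8.85e-05; adjusted p = 0.956 with an estimated correlation). Of the genes that rose with AICAR in sh-con, 94.4% had a change above 0 in sh-p53 (median 0.60 in sh-con, 0.47 in sh-p53), and 1168 of 2023 were called higher there too. The slope over called genes was 0.823, and across genes the responses correlated at Pearson r = 0.847 and Spearman rho = 0.798. These genes too were chosen by their call in sh-con, which by itself favours a larger change there.

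In all, 42 genes had a positive and 98 a negative interaction with AICAR. Quantile normalisation of the arrays again gave 174 and 282, and centring each array on its median gave 47 and 174. Of the main calls, 71 of the 98 were among the 377 with a negative interaction with Nutlin, against 2.67 for independent lists. Both interactions used the same DMSO arrays, so part of that excess can come from the shared controls. In 50 simulations with the fitted interaction for Nutlin and none for AICAR, a test added after the overlap had been seen, the 98 strongest negative AICAR interactions held 25.8 genes negative for Nutlin on average and 36 at most. The counts also moved with single arrays. Positive genes numbered 3 without sh-con DMSO array 1, 8 without sh-con DMSO array 2, 8 without sh-p53 DMSO array 1, 5 without sh-p53 DMSO array 2, 73 without sh-con AICAR array 1, 14 without sh-p53 AICAR array 1 and 9 without sh-p53 AICAR array 2. Negative genes numbered 38 without sh-con DMSO array 1, 43 without sh-con DMSO array 2, 40 without sh-p53 DMSO array 1, 35 without sh-p53 DMSO array 2, 64 without sh-con AICAR array 1, 170 without sh-con AICAR array 2, 37 without sh-p53 AICAR array 1 and 59 without sh-p53 AICAR array 2.

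The last comparison set Nutlin directly against AICAR in sh-con. Cell cycle genes were lower with Nutlin, with SPC25 at -4.96 ± 0.20 (SE, 2 arrays against 2, adjusted p = 4.42e-12), CDK1 at -4.86 ± 0.20 and CCNE2 at -4.29 ± 0.19, as was MUC13 at -4.62 ± 0.18. ABCA12 (3.38 ± 0.13, adjusted p = 3.71e-12), PLCB1 (3.34 ± 0.16) and LYVE1 (3.30 ± 0.18) were higher with Nutlin. The mean of ABCA12 with AICAR, and those of SPC25, CDK1, CCNE2 and MUC13 with Nutlin, lay below the level used to leave out dim genes, so the size and rank of these differences are uncertain. Among p53 targets PMAIP1 was lower with Nutlin (-2.91 ± 0.18), and SPATA18 (2.18 ± 0.17), MDM2 (0.90 ± 0.14, adjusted p = 4.49e-05) and CDKN1A (0.58 ± 0.13, adjusted p = 0.00238) were higher. All 48 mitosis and all 42 S phase genes were lower with Nutlin, also adjusted over the list alone, with medians of -2.94 and -1.88 (camera, adjusted p = 2.45e-55 and 5.46e-37; adjusted p = 0.185 for both with an estimated correlation). Of 19 cholesterol synthesis genes 14 were lower and 1 higher with Nutlin, as adjusted over the list alone, IDI1 (-1.76 ± 0.14) and ERG28 (-1.30 ± 0.13) among them (median -0.85, adjusted p = 1.42e-06; adjusted p = 0.775 with an estimated correlation). Of 37 amino acid response genes 20 were higher and 3 lower, as adjusted over the list alone, SLC7A11 (2.52 ± 0.19) and ATF4 (1.83 ± 0.15) among them (median 0.53, adjusted p = 7.89e-05; adjusted p = 0.775 with an estimated correlation). In all, 2467 genes were higher and 2338 lower with Nutlin.

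Both compounds raised 634 genes in sh-con, against 229 for independent lists, and lowered 1275, against 606. Opposite calls numbered 129 (Nutlin higher, AICAR lower; 362 for independent lists) and 198 (383). The same DMSO arrays entered both comparisons. Unchanged groups simulated against shared, also simulated, DMSO arrays had no calls in common in any of 50 draws. That outcome was nearly fixed, because the simulated data held no changed genes. It therefore does not show how far the shared arrays add to the overlap of real responses. Across genes the responses to the compounds correlated at Pearson r = 0.378, below the mean of 0.499 in the simulation, whereas their covariance was 0.129 against 0.0127, a difference of 0.117. The 2 DMSO arrays were not split between the compounds, so part of the excess overlap can come from the shared controls. The 1909 genes called in the same direction became 745 without sh-con DMSO array 1 and 1027 without sh-con Nutlin array 2.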

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

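The tests of an action of Nutlin unrelated to p53 target genes, of p53 activity left after knockdown, of the scaling of the arrays and of cell cycle genes as a group were chosen after the results they address had been seen.

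The response to Nutlin differed between the lines by the interaction test for 645 genes in the positive and 377 in the negative direction. Positive interactions, in log2 units, were H2BC14 4.07, SPC25 3.91, CLSPN 3.75, H2AC4 3.70, CDC6 3.68, DTL 3.61, PBK 3.59, H3C2 3.50, NUF2 3.34 and CDK1 3.28. Negative ones were ABCA12 -3.83, PLTP -3.57, LYVE1 -3.45, CLTRN -3.35, CSTA -3.26, LCN15 -3.08, TP53I3 -3.05, FRMPD2 -2.97, TRIM22 -2.71, CYP4F3 -2.02, G6PC1 -1.81 and CDKN1A -1.46. The size is uncertain for ABCA12, LYVE1, CLTRN, FRMPD2 and TRIM22, below the dim level in 3 of the 4 groups, and for SPC25, CLSPN and CDK1, below it in sh-con with Nutlin. List medians were 2.46 for mitosis, 1.79 for S phase, 0.491 for ribosome biogenesis and 0.319 for purine and pyrimidine synthesis genes. They were -0.789 for p53 targets, -0.281 for endothelial markers and -0.209 for P450 and drug metabolism genes. These list calls were lost with an estimated correlation, with adjusted p = 0.0809 for mitosis and S phase, 0.667 for ribosome biogenesis, 0.713 for purine synthesis, 0.113 for p53 targets, 0.209 for endothelial markers and 0.437 for P450 genes, and that of the endothelial markers also with the stricter filter on dim genes (adjusted p = 0.671). The gene counts moved with single arrays: 411 positive without sh-con DMSO array 1 and 420 without sh-p53 DMSO array 1, and 239 negative without sh-con DMSO array 2, 233 without sh-p53 DMSO array 1 and 247 without sh-con Nutlin array 1.

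The response to AICAR differed between the lines for 42 genes in the positive and 98 in the negative direction. Left out in turn, sh-con DMSO arrays 1 and 2 gave 3 and 8 positive genes, sh-p53 DMSO arrays 8 and 5, sh-con AICAR array 1 73, and sh-p53 AICAR arrays 14 and 9. Negative genes in the same order numbered 38 and 43, 40 and 35, 64 without sh-con AICAR array 1 and 170 without array 2, and 37 and 59. Negative interactions were CABYR -3.57, TP53I3 -2.49, CLTRN -2.49, CSTA -2.33, LACC1 -2.31, ZSCAN4 -2.25, HCAR3 -2.23, FBXW7 -2.08, KITLG -1.88, TRIM22 -1.73 and NUPR1 -1.51. The size is uncertain for CABYR, CLTRN, LACC1, ZSCAN4 and TRIM22, below the dim level in DMSO in both lines, and for KITLG, below it in sh-con DMSO. Positive ones that kept their call with any array left out were HCFC1 1.66, PLAU 1.55 and BAHD1 1.26. FAM111B (1.39) lost its call without sh-con DMSO array 1 (adjusted p = 0.163) or array 2 (0.0904), sh-p53 DMSO array 1 (0.131) or array 2 (0.119), sh-con AICAR array 2 (0.0728), or sh-p53 AICAR array 1 (0.0782) or array 2 (0.146), and also without the filter on dim genes (0.0549) or with each array centred on its median (0.085). SNORA20 (1.16) lost its call without sh-con DMSO array 1 (0.0924) or array 2 (0.102), sh-p53 DMSO array 1 (0.121), or sh-p53 AICAR array 1 (0.0524) or array 2 (0.101). GPER1 (1.15) lost it without sh-con DMSO array 1 (0.0636), sh-p53 DMSO array 2 (0.0735) or sh-p53 AICAR array 2 (0.0558). CAD (1.14) lost it without sh-con DMSO array 1 (0.0609) or sh-p53 DMSO array 2 (0.0782), and CRYBG1 (1.28) without sh-con DMSO array 1 (0.0609). List medians were -0.465 for p53 targets (adjusted p = 0.552 with an estimated correlation), and 0.359 for S phase, -0.302 for glycolysis and hypoxia response and 0.282 for fatty acid and triglyceride synthesis genes (adjusted p = 0.956 with an estimated correlation for each). The call of the fatty acid list was also lost without sh-con AICAR array 2 (median 0.195, adjusted p = 0.0608).

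Probe sets without a single gene name, which entered none of the comparisons of genes, were tested apart. Of 7623 bright enough to test with limma, 481 were called with Nutlin in sh-con (115 higher, 366 lower), 1634 with AICAR in sh-con (1024 higher, 610 lower) and 1748 with AICAR in sh-p53 (1063 higher, 685 lower). The hairpin in DMSO gave 3, Nutlin in sh-p53 and the interaction with AICAR 0 each, the interaction with Nutlin 46 (33 positive, 13 negative) and Nutlin against AICAR 1312 (348 higher, 964 lower).

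Nutlin moved genes in sh-p53 in the direction of sh-con but by less, with a slope of 0.19 over the genes called in sh-con. A single deviating sh-p53 Nutlin array was argued against, because the slope was 0.143 from sh-p53 Nutlin array 1 alone and 0.238 from array 2 alone. Both slopes used the same sh-p53 DMSO arrays, so a deviating DMSO array was not tested. An action of Nutlin unrelated to p53 target genes, as the whole cause, was also examined. The p53 target genes called in sh-con had a median of 0.363 in sh-p53. Other genes matched on their rise in sh-con had a median of 0.188, a difference of 0.174 (bootstrap SD 0.0448). The bootstrap drew genes, which are not independent, so this SD does not measure the spread between arrays. The difference goes against such an action as the whole cause but does not settle it. Of 55 p53 target genes higher in sh-con, 52 (94.5%) lay above 0 in sh-p53, against 79.2% of 1508 other genes not matched on their rise in sh-con, and 47 of 55 genes (85.5%) that were matched (Fisher's exact test, 2-sided p = 0.202, with genes that are not independent). As a hypothesis, p53 activity left after knockdown may contribute and stays open. The matched shares, both high, did not differ past the threshold, whereas the matched medians differed in the direction of this hypothesis. These measures do not decide it, and the level of the targeted transcript was not analysed here.

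Fewer genes were called higher than lower in sh-con, 37.4% of the calls with Nutlin and 38.7% with AICAR. With AICAR this was limited to named genes. Of the probe sets without a single gene name, 1024 were higher and 610 lower with AICAR, and 115 higher and 366 lower with Nutlin. Without the 90 S phase and mitosis genes the shares were 38.2% and 38.7%, but so few genes could not have moved them to near 50% (at most 38.2% and 39.4%), so lower cell cycle genes beyond these lists stay open. Under the other scalings the shares came to between 47.7% and 52.4%, but these also moved the median change of all tested genes away from 0, from 0.0123 to 0.0484 and 0.122 with Nutlin and from 0.0353 to 0.046 and 0.146 with AICAR, so the scaling of the arrays stays open too. No other explanation was tested.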

How the results depend on the processing

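All alternatives in this part were chosen before the data were examined. Nutlin against AICAR moved by over 1.5 times under 1 setting only, a minimum of 1.5-fold (1612 higher). Counts from that minimum, which can only remove calls, were 770 and 1574 for Nutlin in sh-con, 1060 and 2113 for AICAR in sh-con, 1116 higher for AICAR in sh-p53 and 880 for the overlap. For the other settings the cause was not tested. Fitting only the arrays compared gave 63 and 112 genes for the hairpin in DMSO, 2491 higher for Nutlin in sh-con, and 29 and 38 for Nutlin in sh-p53. Without moderation the hairpin gave 8 and 10, Nutlin in sh-con 986 higher, Nutlin in sh-p53 4 higher, its interaction 396 and 199, the AICAR interaction 0 and 3, and the overlap 1265. Quantile normalisation again gave 19 and 4 for Nutlin in sh-p53, 664 negative for its interaction, and 174 and 282 for the AICAR interaction. Centring gave 174 negative for the AICAR interaction. The stricter filter gave 12 lower for Nutlin in sh-p53 and 94 positive for the AICAR interaction. The trended and robust prior gave 10 lower and 98 and 176.

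With 1 array left out, a lone array is assumed to vary like the other groups. The ranges of genes higher and lower were 22 to 52 and 20 to 75 for the hairpin, 737 to 1976 and 1324 to 2866 for Nutlin in sh-con, 1164 to 2562 and 2009 to 3409 for AICAR in sh-con, 5 to 14 and 0 to 9 for Nutlin in sh-p53, and 1382 to 2638 and 1925 to 3166 for AICAR in sh-p53. They were 411 to 809 and 233 to 480 for the Nutlin interaction, 3 to 73 and 35 to 170 for the AICAR interaction, 1702 to 2482 and 1688 to 2351 for Nutlin against AICAR, and 745 to 2421 for the overlap. With Nutlin in sh-p53, the median of the NRF2 list turned to -0.0129 without sh-p53 DMSO array 1 (up to 0.123 otherwise) and that of the autophagy list to -0.0412 without sh-p53 Nutlin array 1 (up to 0.177).

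Of the named genes' values, 2624 kept their side of the threshold with 1 array left out, 48 lost a call and 4 gained one. Without moderation 36 lost it, without the filter 2, with centring 1 and with every probe set tested 1. Quantile normalisation again, the trended prior, only the arrays compared and the stricter filter gained 2 each. With the stricter filter only 178 kept their side, against 221 after quantile normalisation again, because other named genes were left out as dim and not tested. Of list calls, 58 were lost with an estimated correlation, 32 with 1 array left out, 6 with the stricter filter, 2 with only the arrays compared, 2 with quantile normalisation again and 1 without the filter. Lists were not run without moderation or with the minimum fold. Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at r = -0.558 to 0.567, over 0.1 in 7 of 15 pairs of groups and under -0.1 in 7. The sh-con DMSO, sh-con Nutlin, sh-p53 Nutlin and sh-con AICAR groups correlated positively with each other (0.252 to 0.567). So did sh-p53 DMSO with sh-p53 AICAR (0.264), whereas r between these sets ran from -0.558 to 0.0277. The arrays thus shared a deviation that the numbers do not follow, and a block by number does not model it. With the replicate block the counts were 44 and 63 for the hairpin and 1635 and 2638 for Nutlin in sh-con, no count moved by over 1.5 times, no named gene lost its call and 1 list did (autophagy with AICAR in sh-con, adjusted p = 0.0596). Signal over background limits dim genes, for which RMA values give no detection call.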

Other observations

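The histone, snoRNA and gene length groups, their members named here and the test of reduced transcription through long genes were chosen after the data had been seen. Of 41 replication-dependent histone genes, whose transcripts are made mainly in S phase, 33 fell and 1 rose with Nutlin in sh-con (median -1.38), H2BC14 by a log2 change of -4.69 ± 0.15, H2AC4 by -4.23 ± 0.16, H3C2 by -3.82 ± 0.16 and H4C2 by -3.55 ± 0.17. None passed with Nutlin in sh-p53 with limma (median -0.167; 1 higher and 12 lower at an unadjusted p under 0.05), and 25 had a positive interaction. With AICAR 23 fell and 2 rose in sh-con (median -0.63), and 26 fell and 1 rose in sh-p53 (median -0.951), with H3C2 at -1.86 ± 0.16 and H4C2 at -1.83 ± 0.17 in sh-con. Histone genes of one type are near-identical, so a probe set can measure several of them.

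Small nucleolar RNA genes guide the modification of ribosomal RNA and mostly lie in introns of host genes. Of 132 tested, 57 fell and 1 rose with Nutlin in sh-con and the others did not pass with limma (median -0.364, and -0.334 and -0.254 under the other scalings), SNORD30 by -2.13 ± 0.15 and SNORD12C by -1.73 ± 0.18 among them, and 24 had a positive interaction with the hairpin. None passed with Nutlin in sh-p53 with limma (median -0.0479; 7 higher and 9 lower at an unadjusted p under 0.05). With AICAR 56 fell and 14 rose in sh-con (median -0.348), with SNORD12C at -3.17 ± 0.18, SNORD49A at -2.95 ± 0.23 and SNORD34 at -2.63 ± 0.21, and 62 fell and 15 rose in sh-p53 (median -0.451). A probe set for a small nucleolar RNA can also measure the unspliced host transcript. Neither the histone nor the small nucleolar RNA genes were tested as a group against other genes.

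Long genes were lower with AICAR. Among 12932 protein-coding genes with a locus length, the median change went from 0.213 in the shortest 10% of genes to -0.643 in the longest 10% (139 kb or more) in sh-con, and from 0.223 to -0.586 in sh-p53. In the longest 10%, 801 of 1294 genes (61.9%) fell in sh-con and 795 (61.4%) in sh-p53, PTPRK (-3.17, 552 kb), PRKCA (-3.12, 508 kb) and PLCB1 (-3.02, 753 kb) in sh-con among them. The gap between the longest 10% and the other genes was -0.701 in sh-con and -0.68 in sh-p53, against -0.0857 and -0.06 with Nutlin, where length had a weaker trend (Spearman rho = -0.181 and -0.21, against -0.387 and -0.401 with AICAR) and the median in sh-con went from 0.193 in the shortest 10% to -0.0765 in the longest, with -0.118 in the group before it. It was -0.634 and -0.642 after quantile normalisation again, and lay between -0.796 and -0.564 in sh-con with 1 array left out.

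Signal level was argued against as the whole cause of this length pattern, because the mean gap over 10 groups of genes of matched signal was -0.59 in sh-con and -0.595 in sh-p53. It lay under -0.3 in 8 of the 10 in each line, and ranged from -0.893 to -0.0733 and from -0.991 to -0.0792, closest to 0 in the dimmest group. Variation between duplicate arrays was argued against too, since the largest such gap between the 2 arrays of a group was 0.131. A deviation shared by the arrays of a treatment does not show in that difference and was not tested. With genes split by length into 10 equal groups, each of the upper 5 had a lower median than the group before it in both lines with AICAR, which restates the pattern, and also with Nutlin in sh-p53. Reduced transcription through long genes, a hypothesis drawn from the pattern, stays open, because the arrays hold no measure of it. Faster decay of the transcripts of long genes stays open for the same reason. Length here was that of the locus, and the length of the transcripts was not examined.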
